A study of Mus musculus with 58 samples.

How the data were processed

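Bulk RNA sequencing had been done on prefrontal cortex of C57BL/6J mice that the labels give as heterozygous for Kmt5b, the gene of a histone H4 lysine methyltransferase, or as wild-type, here HT and WT. Pups received vehicle, fluoxetine or lithium for 3 weeks through maternal milk, from postnatal day 3 to 24, and tissue was taken on postnatal day 25. Libraries were stranded and poly(A)-selected. The 58 libraries fell into 12 groups of genotype, treatment and sex, with 5 libraries in each of 10 groups and 4 each in WT lithium females and WT lithium males. Groups were taken from the labels alone. The labels gave no litter, and littermates share a treatment when it comes with the milk, so the p values may be smaller than they would be with litter in the model.

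The submitters' processing notes named Salmon 0.11.2, R 3.6.0, DESeq2 1.19.11 and the genome build GRCm38, without stating the annotation release. The authors deposited 1 table of 18088 Ensembl genes by 58 libraries, a normalised signal per gene and library. Every nonzero value of a library was a whole multiple of 1 step within a tolerance of 0.01, in 100% of values, as gene counts divided by 1 size factor per library would be. The value of 1 read ranged from 0.75 to 1.27, and the recovered reads per library from 23.5 to 38.6 M with a median of 27.6 M. The 10 genes with the most reads took 6.6% to 10.7% of a library. For 4 libraries (HT lithium male 3, HT vehicle female 2, HT vehicle male 1 and HT vehicle male 5) the step lay too close to 1 for the unit check to decide. Their values were whole multiples of a step too, but tests on counts were run on the other 54. All 4 were labelled HT, and all but HT lithium male 3 were HT vehicle. Results on 54 libraries therefore rest on fewer HT vehicle libraries than the main results.

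Gene symbols, positions and exon lengths came from the supplied annotation: 18077 IDs had a symbol and 11 had none. Values were put on a log2 scale after adding 1. Genes with a mean normalised count of at least 10 were tested, which kept 16669 and left out 1419. limma 3.58.1 (R 4.3.3) fitted 1 coefficient per group over all 58 libraries, with a trend of the variance on the mean, and comparisons between treatments or genotypes averaged both sexes. Benjamini-Hochberg adjustment ran over all genes tested, and a gene passed at an adjusted p under 0.05. The plan foresaw a test for counts and a test for normalised values, and the second applied. The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined.

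Named genes were Kmt5b and, in each of 6 main comparisons, the 12 higher and the 12 lower genes with the smallest p among those that passed with the same sign in both sexes. Where fewer than 5 genes passed, those with the smallest p were to be named. For interactions and sex differences, 3 each way were named. For each list described, up to 4 members with the smallest p in that comparison were named. Some genes that this rule picks are not reported here. Predicted genes and pseudogenes without an assigned function were counted and not named. Pisd-ps1 and Pisd-ps2 fall outside that rule and were chosen after their values were seen. In the text, rose and fell are used of genes that passed.

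Of 35 gene lists, 34 were tested with camera at a preset correlation of 0.01 in 7 comparisons, which made 238 tests adjusted together. The list of sex-linked genes served only to check labels. Each list was tested again with a correlation estimated from its own genes, and with fry, which asks whether a list's genes move at all, without comparing them with other genes. Counts of members that passed are given over all genes tested and, in those words, adjusted over the list alone. They are not a test of enrichment, since many genes outside the lists also passed in the drug comparisons.

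Differences of library measures between groups, and of Kmt5b between genotypes, were tested with two-sided permutation tests of 100000 resamples, exchanging libraries within sex (for Kmt5b within sex and treatment). Correlations between 2 effects were computed across genes, which are not independent replicates. They were compared with 100 draws in which residuals were permuted between libraries within sex, and with 100 splits in which the vehicle libraries shared by both effects were divided between them. The permutation p printed with a correlation is that of the covariance of the 2 effects, and r itself was not tested. Genes in common between comparisons were set against 100 draws, the real data included, of the same permuted residuals over all 58 libraries.

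The alternatives planned were quantile normalisation, limma without the trend, no filter, a mean of at least 100, pseudocounts of 0.5 and 10, a fit on the compared groups alone, the replicate number as a block, a striatal marker covariate, and leaving out each library in turn. Chosen after seeing the data were a covariate for the level of 4 olfactory bulb markers, a covariate for each library's slope of log2 level on log2 exon length, both together, 2 surrogate variables on the log2 values, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads of 54 libraries beside limma on the same 54, and leaving out 4 libraries in either of 2 definitions. The same 4 olfactory bulb markers gave the olfactory bulb level of each library, as a mean log2 difference from all libraries. In negative binomial counts simulated from the mean and spread of each gene, with changes put into 200 genes, changes of 1.5-fold were recovered in 88.1% of genes for the genotype comparison under vehicle, 85.1% for fluoxetine in HT and 68.7% for lithium in WT, with 6, 5 and 4 false calls. At 1.25-fold the share was 62.7%, 59.7% and 64.2%. These counts were drawn independently for each gene and library, without structure shared between genes. Other splits of the real libraries passed up to 890, 1296 and 2023 genes in these comparisons, so the false calls given describe the simulation alone. No library was left out of the main results, and no sample columns were unused.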

Results

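Prefrontal cortex of 58 mice was profiled by RNA sequencing on postnatal day 25. There were 10 libraries each of WT vehicle, WT fluoxetine, HT vehicle, HT fluoxetine and HT lithium, and 8 of WT lithium, with the sexes in equal numbers. Library depth lay between 23.5 and 38.6 M recovered reads. Xist and Ddx3y went against the sex label in 0 of 58 libraries. No pair of replicates was as alike as sampling noise alone would make it, the ratio of their difference to that noise being 2.92 to 57.4 over 112 pairs.

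Kmt5b, the gene the genotype labels refer to, was read first to check the labels. Its normalised count was 1734 ± 98.3 (SD, n = 30) in libraries labelled HT and 1654 ± 137 (SD, n = 28) in libraries labelled WT, so the libraries labelled HT did not have less Kmt5b RNA. The gene (ENSMUSG00000045098) lies on chromosome 19 from 3767421 to 3818303. The difference was 0.07 on the log2 scale (SE 0.0251, 95% confidence interval 0.02 to 0.13), a fold of 1.05, with p = 0.00466 by limma, p = 0.00778 by permutation and adjusted p = 0.186 over all genes. Under vehicle the difference was 0.08 (SE 0.0427, adjusted p = 0.435), under fluoxetine 0.01 (adjusted p = 0.966) and under lithium 0.13 (SE 0.0453, adjusted p = 0.27). The table holds 1 value per gene, so transcripts of an allele that lacks part of the gene were not told apart from intact ones. With the olfactory bulb level, the exon length slope, both or 2 surrogate variables in the fit, settings chosen after seeing the data, Kmt5b was higher in HT at an adjusted p under 0.05. HT and WT therefore stand for libraries so labelled throughout, and in every comparison of HT with WT the direction rests on the labels. The related gene Kmt5c stood at 526 ± 30.9 (SD, n = 10) in HT vehicle and 476 ± 58.5 (SD, n = 10) in WT vehicle, and the gene list of the KMT5 family and readers of its mark passed in 0 of 7 comparisons by camera.

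**Figure D1:**
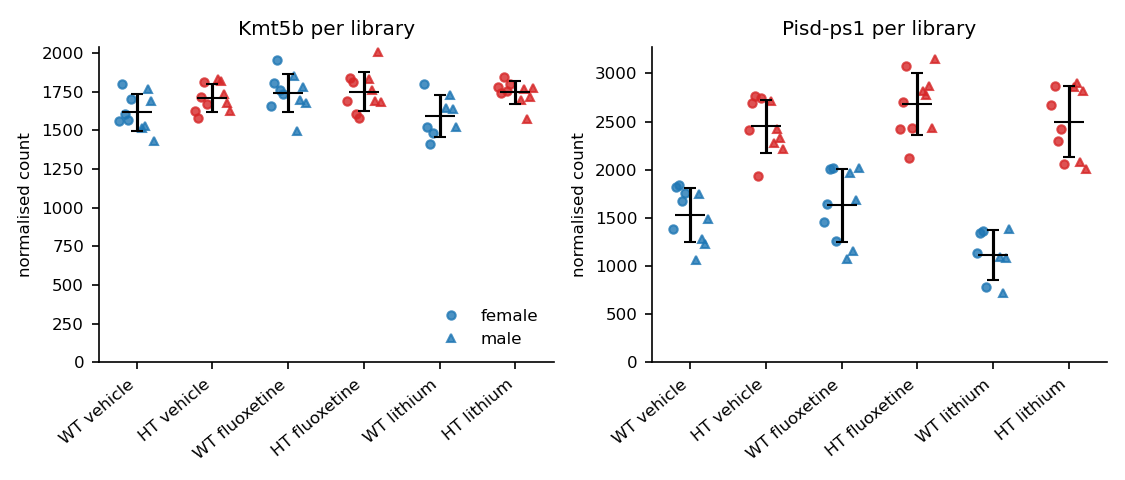
Normalised counts (linear axes from 0) of Kmt5b and Pisd-ps1 in each library by group, with circles for females, triangles for males, and the mean ± SD in black. Kmt5b averaged 1734 in HT and 1654 in WT, and Pisd-ps1 averaged 2544 in HT and 1445 in WT.

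The comparison of HT with WT under vehicle asks what the genotype does without a drug. Slco1a4, an organic anion transporter of the blood-brain barrier, fell from 1707 ± 188 in WT to 1338 ± 123 in HT (SD, n = 10 each), a log2 difference of -0.35 (SE 0.0576, limma adjusted p = 0.00133). Asah1 (-0.17), the lysosomal acid ceramidase, and Rnf141 (-0.17) also fell. Matn2 (0.35), an extracellular matrix protein, Tmem28 (0.24) and P4ha3 (0.46), a subunit of collagen prolyl 4-hydroxylase, rose, each at adjusted p = 0.0394, and so did Pisd-ps1 (0.70, adjusted p = 0.00133). In all 5 genes rose and 3 fell of 16669, 2 of the 8 being predicted genes or pseudogenes, and 2035 genes had an unadjusted p under 0.05. The count was 1 when the compared groups were fitted alone, 2 with the replicate number as a block and 0, 1 and 7 by limma, edgeR and DESeq2 on 54 libraries. Without 4 libraries, in 2 sets chosen after seeing the data, it was 235 (67 higher and 168 lower) and 93 (29 higher and 64 lower). It was 25, 17 and 14 without HT vehicle male 3, female 1 and female 4, 22 without WT vehicle male 2, and 2 to 4 without any 1 of the other libraries except HT vehicle female 2, WT vehicle female 4 and WT vehicle male 3, without which it stayed within 1.5 times.

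Among gene lists under vehicle, mitochondrially encoded genes were lower in HT, with 0 of 15 members above WT and a median log2 difference of -0.305. None passed over all genes, and 13 fell adjusted over the list alone, for example mt-Nd6 (-0.31, adjusted p = 0.071) and mt-Nd4 (-0.31, adjusted p = 0.111). Camera gave adjusted p = 3.43e-15, and adjusted p = 0.2 with an estimated correlation. The share of normalised counts on these genes was 6.76% ± 0.66 in HT vehicle and 7.90% ± 0.70 in WT vehicle (SD, n = 10 each, permutation p = 0.00111, adjusted p = 0.0113 over 20 tests). Cell cycle genes were higher in 29 of 31 members (median 0.26, camera adjusted p = 2.77e-07, and adjusted p = 0.352 with an estimated correlation). Of these 0 passed over all genes or adjusted over the list alone, and the smallest p were those of Tpx2 (0.32, adjusted p = 0.197) and Kif20a (0.42, adjusted p = 0.268). Microglia markers (camera adjusted p = 8.46e-05, median -0.0757) and GABA receptor genes (camera adjusted p = 0.0241, median -0.0446) were lower, with 3 and 5 members that fell adjusted over the list alone and 0 over all genes. With an estimated correlation these had adjusted p = 0.691 and 0.67. The microglia call ended with the olfactory bulb level as a covariate (adjusted p = 0.0524), and the GABA receptor call with that level (0.0974), with the exon length slope (0.052) or with a mean of at least 100 (0.0531), where the cell cycle call also ended (0.05). These covariates were chosen after seeing the data. Olfactory bulb and thalamus markers were higher in 16 of 20 members (median 0.307, 1 risen adjusted over the list alone and 0 over all genes, camera adjusted p = 0.00401, and adjusted p = 0.714 with an estimated correlation), and the olfactory bulb level of HT vehicle libraries was 0.96 ± 0.74 against -0.66 ± 2.25 in WT vehicle (SD, n = 10 each, permutation p = 0.0538).

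Averaged over the 3 treatments, 65 genes were higher and 13 lower in HT. The higher genes named were F2r (0.29, the thrombin receptor), P4ha3 (0.35), Col5a1 (0.27, a fibrillar collagen chain), Gsto1 (0.15), Ccdc80 (0.18), Nipsnap3b (0.19), Cd44 (0.31, the hyaluronan receptor), Pisd (0.13), Map3k15 (0.34), S100a10 (0.16), Mctp2 (0.45) and Npnt (0.20, an extracellular matrix protein), with adjusted p from 4.95e-05 (F2r, SE 0.0418) to 0.00354. Those that fell were Gzf1 (-0.10, SE 0.017, adjusted p = 0.00175), Samd4 (-0.15), Zfp277 (-0.11), Bag4 (-0.11), Sec23b (-0.07), Ipo9 (-0.09), Sdf4 (-0.07), Slc7a10 (-0.16), Polr2b (-0.08), Bsdc1 (-0.06), Pik3cb (-0.09) and Trappc11 (-0.07), so that differences were small. Pisd-ps1, a transcribed pseudogene of the phosphatidylserine decarboxylase gene Pisd, had the clearest difference. Its normalised count was 2544 ± 329 in HT (SD, n = 30) and 1445 ± 371 in WT (SD, n = 28), a log2 difference of 0.88 (SE 0.0673, adjusted p = 1.12e-13). It lies on chromosome 11 from 3125904 to 3131004. Pisd-ps2 on chromosome 17 from 3076578 to 3084183 rose by 0.44 (adjusted p = 7.77e-07), and reads shared among these copies leave the level of each copy uncertain. The lists were also run in this comparison after the data were seen: striatal projection neuron markers (camera adjusted p = 1.43e-05) and cell cycle genes (camera adjusted p = 0.000113) were higher with 0 members past the threshold over all genes (1 and 0 risen adjusted over the list alone), and with an estimated correlation adjusted p = 0.212 and 0.593. Serotonin and monoamine genes were also higher (camera adjusted p = 0.00047, 0 risen over all genes and 2 adjusted over the list alone, and adjusted p = 0.0801 with an estimated correlation). Lower by camera were presynaptic genes (adjusted p = 0.00434, 1 risen adjusted over the list alone), heat shock chaperones (0.00508, 2 fallen adjusted over the list alone), blood markers (0.00647), astrocyte markers (0.00873, 1 fallen over all genes and over the list alone), nuclear genes of oxidative phosphorylation (0.0098), GABA receptors (0.0334) and glutamate receptors (0.0425), and with an estimated correlation their adjusted p was 0.593 or more. The count of 78 was 225 with the exon length slope as a covariate, 42 after quantile normalisation and 122 without WT lithium female 1.

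Under fluoxetine, 64 genes were higher and 38 lower in HT than in WT, and under lithium 8 were higher and 2 lower. Pisd-ps1 rose in both (0.75 under fluoxetine, and under lithium with adjusted p = 3.75e-09), and Pisd-ps2 rose under lithium (0.60, adjusted p = 0.000983). The count under fluoxetine was 7 when the compared groups were fitted alone. More genes were lower than higher with 2 surrogate variables (180 higher and 265 lower), with the olfactory bulb level as a covariate (105 and 120) and without the first set of 4 libraries (78 and 119), all chosen after seeing the data. Without 1 HT fluoxetine library the count was 46 (female 1), 172 (female 3), 26 (female 4), 11 (female 5 or male 1) and 67 (male 5), and without 1 WT fluoxetine library 57 (female 1), 15 (female 2 or male 4), 63 (female 5) and 33 (male 5). The count under lithium was 211, 28 and 17 without WT lithium female 1, female 2 and male 1, 7 without HT lithium female 4 or male 1, and 2 to 5 without any 1 of the other libraries.

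**Figure D2:**
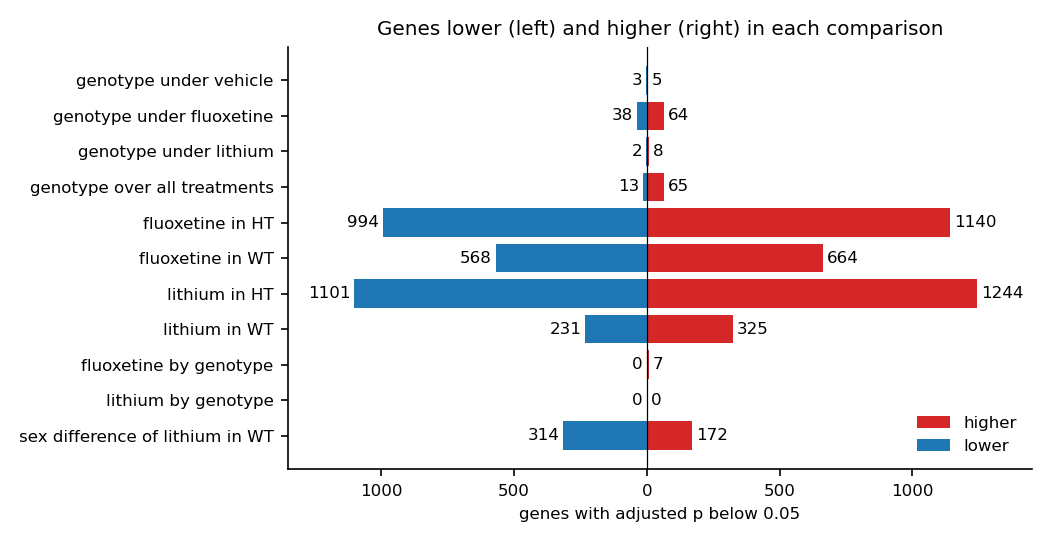
Genes lower (blue, left) and higher (red, right) at adjusted p under 0.05 in each comparison, on a linear axis of gene counts, with higher and lower taken in HT against WT, in drug against vehicle, in the drug effect of HT against WT, and in the drug effect of males against females. The drug comparisons held 556 to 2345 genes and the genotype comparisons 8 to 102.

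Fluoxetine against vehicle in HT asks what the drug does in mice labelled HT. Hif3a, a hypoxia-inducible factor subunit, rose from 144 ± 41.9 to 302 ± 76.3 normalised counts (SD, n = 10 each), a log2 difference of 1.07 (SE 0.145, adjusted p = 8.03e-06). Chrm4, a muscarinic acetylcholine receptor, fell from 436 ± 37.0 to 283 ± 57.2 (-0.64, SE 0.0783, adjusted p = 1.03e-06). In all 1140 genes rose and 994 fell, 126 of them by over 1.5-fold. Others that rose were Paqr8 (0.33), a membrane progesterone receptor, Mertk (0.55), a phagocytic receptor kinase, Reep3 (0.33), Crot (0.29), Kcnj2 (0.54), an inward rectifier potassium channel, Ccdc141 (0.49), Sgms1 (0.32), a sphingomyelin synthase, P2ry13 (0.45), Sppl2a (0.21), Sypl (0.34) and Glrx2 (0.20). Others that fell were Stk40 (-0.39), Efnb1 (-0.42), Nab2 (-0.57), Bahd1 (-0.24), Klf16 (-0.30), Zfp553 (-0.27), the clock gene Per1 (-0.52), Ier5l (-0.81), Dnajb5 (-0.36), Nr4a3 (-0.80) and Klf10 (-0.71). The adjusted p of the named genes was at most 0.000199. The count was 1353 without HT vehicle female 3, 4088 with the olfactory bulb level as a covariate, and 789, 783 and 1002 by limma, edgeR and DESeq2 on 54 libraries.

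Immediate early genes, which respond to neuronal activity, were lower with fluoxetine in HT. Of 32 members 21 fell and 11 did not pass (24 fell adjusted over the list alone), among them Nr4a3, Fosl2 (-0.62) and Junb (-0.89). Camera gave adjusted p = 4.78e-15, and adjusted p = 0.2 with an estimated correlation. Of 25 cholesterol biosynthesis genes 12 fell and 13 did not pass (14 fell adjusted over the list alone), for example Srebf2 (-0.22), a transcriptional activator of the pathway (camera adjusted p = 1.55e-10, and adjusted p = 0.352 with an estimated correlation). Mitochondrially encoded genes rose in 10 of 15 members and 5 did not pass (12 rose adjusted over the list alone), such as mt-Nd6 (0.34) and mt-Nd4l (0.81), with camera adjusted p = 1.14e-08 and adjusted p = 0.494 with an estimated correlation. Their share of counts was 7.97% ± 0.66 with fluoxetine against 6.76% ± 0.66 with vehicle (SD, n = 10 each, permutation p = 0.00113, adjusted p = 0.0113). The HT vehicle share was the lowest of all groups of genotype and treatment, the others averaging 7.33% to 7.97%. In WT the share was 7.39% with fluoxetine and 7.33% with lithium, against 7.90% with vehicle. Genotype under vehicle, both drug effects in HT and both genotype by drug tests contain the same HT vehicle libraries. Their results, for this list and for others, are not independent of each other.

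Markers of several cell types also moved in HT with fluoxetine. Oligodendrocyte and myelin markers rose in 11 of 33 and 22 did not pass (12 rose adjusted over the list alone), such as Mal (0.62) and Ermn (0.59), with camera adjusted p = 1.33e-05 and adjusted p = 0.823 with an estimated correlation. Microglia markers rose in 7 of 27 (10 adjusted over the list alone), such as P2ry12 (0.30), and astrocyte markers in 6 of 25 (10 adjusted over the list alone), such as Gjb6 (0.38). These lists had camera adjusted p = 2.08e-05 and 0.00455, and with an estimated correlation adjusted p = 0.691 and 0.714. Endothelial and mural markers rose in 7 of 29 (8 adjusted over the list alone) and did not pass camera (adjusted p = 0.331, median -0.0102). Inhibitory neuron markers had a median of -0.142, with 1 of 28 risen and 2 fallen over all genes and over the list alone, camera adjusted p = 0.05 (not passed) and fry adjusted p = 0.0199. The fry result is given for this list alone, so it does not set this list apart from others. Cytosolic ribosomal protein genes fell in 17 of 82 (22 adjusted over the list alone), for example Rpl36 (-0.37), and nuclear genes of oxidative phosphorylation in 18 of 77 (21 adjusted over the list alone), for example Ndufa13 (-0.29). Camera gave adjusted p = 7.41e-10 and 8.2e-10, and with an estimated correlation adjusted p = 0.717 and 0.714. Glucocorticoid-responsive genes went both ways, 4 of 20 having risen and 5 fallen (7 and 5 adjusted over the list alone, camera adjusted p = 0.551).

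Fluoxetine in WT gave the same comparison in mice labelled WT. Hif3a rose from 145 ± 39.6 to 360 ± 75.8 (1.32, SE 0.145, adjusted p = 2.25e-08), and Insig1, which restrains sterol synthesis in the endoplasmic reticulum, fell by 0.52 (SE 0.0568, adjusted p = 2.25e-08). In all 664 genes rose and 568 fell. Others that rose were Dnajc3 (0.36), an endoplasmic reticulum co-chaperone, the transcription factor Zbtb16 (0.89), Ccdc141 (0.58), Piga (0.50), Adam8 (0.66), Atp10a (0.68), Acap2 (0.30), Igf1r (0.38), the receptor of insulin-like growth factor, Mcf2l (0.28), Fkbp5 (0.86), a co-chaperone of the glucocorticoid receptor, and Dapk1 (0.29). Others that fell were Depp1 (-1.89), Stk40 (-0.43), Klf10 (-0.95), Ier5l (-0.97), Klf16 (-0.34), Phf13 (-0.45), Arid5a (-0.42), Arl4d (-0.74), Dusp1 (-1.04), a phosphatase of MAP kinases, Dyrk3 (-0.59) and Cyp51 (-0.35), an enzyme of cholesterol synthesis. The adjusted p of the named genes was at most 5.21e-05. The count of 1232 was 273 with the exon length slope as a covariate, of which 254 were among the 1232, and 668, 724 and 746 without WT vehicle female 4, WT vehicle female 1 and WT vehicle male 5. That slope was 0.0215 ± 0.0163 with fluoxetine and -0.0137 ± 0.0419 with vehicle (SD, n = 10 each, permutation p = 0.0163, adjusted p = 0.0768).

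In WT with fluoxetine, cholesterol biosynthesis genes fell in 22 of 25 members and 3 did not pass (23 fell adjusted over the list alone), such as Sqle (-0.32), with camera adjusted p = 8.32e-26 and adjusted p = 0.0753 with an estimated correlation. Immediate early genes fell in 24 of 32 and 8 did not pass (25 fell and 1 rose adjusted over the list alone), such as Nr4a1 (-1.01), Gadd45b (-0.76) and Junb (-1.17), with camera adjusted p = 3.99e-25 and adjusted p = 0.077 with an estimated correlation. Fos stood at 543 ± 227 with fluoxetine and 1157 ± 229 with vehicle (SD, n = 10 each). Of 33 genes of the unfolded protein and integrated stress response 13 rose, 1 fell and 19 did not pass (15 rose and 8 fell adjusted over the list alone). Manf (0.35), the chaperone Hspa5 (0.44) and Creld2 (0.50), which act in the endoplasmic reticulum, rose (camera adjusted p = 0.00142, and adjusted p = 0.67 with an estimated correlation). Ribosomal protein genes fell in 9 of 82 (32 adjusted over the list alone), such as Rpl13 (-0.17), with camera adjusted p = 4.78e-15 and adjusted p = 0.67 with an estimated correlation. Endothelial and mural markers fell in 3 of 29 (3 adjusted over the list alone), Tek (-0.39), Pltp (-0.33) and Slco1a4 (-0.18), and microglia markers in 3 of 27 (3 adjusted over the list alone), including Ctss (-0.20) and Laptm5 (-0.22). Camera gave adjusted p = 0.000209 and 0.000447, and with an estimated correlation adjusted p = 0.691 and 0.717. Autism risk genes were higher by camera (adjusted p = 0.000486, median 0.0597, and adjusted p = 0.825 with an estimated correlation). Of 118 members 7 rose, such as Zmynd8 (0.28) and Chd2 (0.25), and 2 fell (14 and 2 adjusted over the list alone). Of all 16669 genes tested 664 rose and 568 fell, so these member counts do not by themselves set the list apart. With the exon length slope as a covariate camera gave adjusted p = 0.119 for autism risk genes. The microglia call also ended with that covariate (adjusted p = 0.591).

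The test of whether fluoxetine acts differently in HT and WT passed 7 genes, each with a more positive drug effect in HT in the fit over all libraries. Slco1a4 differed by 0.47 (SE 0.0814, adjusted p = 0.00887). It stood at 1338 ± 123 and 1632 ± 164 in HT without and with the drug, and at 1707 ± 188 and 1503 ± 132 in WT (SD, n = 10 each). This test contains the same vehicle libraries as genotype under vehicle, where Slco1a4 differed by -0.35, so those results are not independent. Mpeg1 (0.32), a macrophage perforin, had adjusted p = 0.0384. Of the others, Nr2e1 (0.48), S1pr1 (0.42), Ctss (0.34) and Gpc5 (0.27), were named after their values were seen. At an unadjusted p under 0.05 there were 1858 genes. The count was 0 when the compared groups were fitted alone, 0, 0 and 24 (13 higher and 11 lower) by limma, edgeR and DESeq2 on 54 libraries, 482 (177 higher and 305 lower) without 4 libraries chosen after seeing the data, and 46, 25 and 11 without HT fluoxetine male 4, HT fluoxetine female 3 and HT vehicle female 2. It was 1 to 4 without any 1 of HT fluoxetine female 1, 4 and 5 and male 1, 3 and 5, HT vehicle female 4 and 5 and male 1 and 4, WT fluoxetine female 1, 3, 4 and 5 and male 1 and 4, and WT vehicle female 1 and 5 and male 1, 4 and 5.

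With lithium against vehicle in HT 1244 genes rose and 1101 fell. Hif3a rose from 144 ± 41.9 to 394 ± 47.1 (SD, n = 10 each), a log2 difference of 1.49 (SE 0.145, adjusted p = 7.63e-10). Ctnnb1, which encodes beta-catenin, fell by 0.31 (SE 0.0372, adjusted p = 1.66e-07). Others that rose were Paqr8 (0.41), Sgms1 (0.43), Mertk (0.62), Paqr5 (1.06), Il1r1 (0.72), the interleukin receptor, Map3k6 (1.18), Nr6a1 (0.44), Smim3 (0.88), Sntb2 (0.52), Acer2 (0.74), an alkaline ceramidase, and Usp53 (0.40). Others that fell were Usp11 (-0.18), Ahcy (-0.25), which hydrolyses S-adenosylhomocysteine, Pnck (-0.38), Vgll4 (-0.28), Psme1 (-0.33), Tmem130 (-0.27), Hunk (-0.42), Vegfc (-0.52), Fads2 (-0.22), a fatty acid desaturase, Pqbp1 (-0.24) and Cyb5r3 (-0.18). The adjusted p of the named genes was at most 2.7e-05. The count stayed within 1.5 times in each of 20 fits without 1 library, and was 1061, 995 and 1258 by limma, edgeR and DESeq2 on 54 libraries.

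In HT with lithium, cell cycle genes fell in 15 of 31 members and 16 did not pass (20 fell adjusted over the list alone), such as Top2a (-1.03), Mcm6 (-0.45) and Mki67 (-0.81), with camera adjusted p = 7.41e-10 and adjusted p = 0.203 with an estimated correlation. Ribosomal protein genes fell in 44 of 82 and 38 did not pass (56 fell adjusted over the list alone), such as Rps26 (-0.26) and Rpl13 (-0.22), with camera adjusted p = 1.19e-19 and adjusted p = 0.608 with an estimated correlation. Cholesterol biosynthesis genes fell in 13 of 25 (16 adjusted over the list alone), such as Fdps (-0.24), with camera adjusted p = 2.77e-08 and adjusted p = 0.479 with an estimated correlation. Of 20 glucocorticoid-responsive genes 8 rose and 12 did not pass (8 rose adjusted over the list alone), such as Zbtb16 (0.82), Sult1a1 (0.94) and Plin4 (1.93), with camera adjusted p = 8.61e-05 and adjusted p = 0.449 with an estimated correlation. Of 22 genes of the Wnt and beta-catenin list 3 fell and 1 rose (3 and 1 adjusted over the list alone): Ctnnb1, Myc (-0.32) and Nkd1 (-0.19) fell and Znrf3 (0.15) rose, with camera adjusted p = 0.0192 and adjusted p = 0.2 with an estimated correlation. Of 23 targets of p53 5 rose and 1 fell (9 and 2 adjusted over the list alone), such as Fas (0.95) and Trp53inp1 (0.52), with camera adjusted p = 0.0455 and adjusted p = 0.207 with an estimated correlation. Oligodendrocyte and myelin markers fell in 4 of 33 (4 adjusted over the list alone), such as Sox10 (-0.36), and oligodendrocyte precursor markers in 3 of 20 (5 adjusted over the list alone), such as Olig2 (-0.28). Camera gave adjusted p = 0.00192 and 0.0222, and with an estimated correlation adjusted p = 0.856 and 0.67. With a mean of at least 100 the calls of the Wnt and beta-catenin list (adjusted p = 0.05), p53 targets (0.0664) and oligodendrocyte precursor markers (0.0671) ended, the last also with the olfactory bulb level as a covariate (0.0838). Endothelial and mural markers went both ways, 2 of 29 having risen and 8 fallen (4 and 10 adjusted over the list alone, camera adjusted p = 0.101). Mitochondrially encoded genes rose in 5 of 15 (10 adjusted over the list alone), such as mt-Nd5 (0.24), with camera adjusted p = 6.36e-05 and adjusted p = 0.691 with an estimated correlation, and their share of counts was 7.66% ± 0.75 with lithium against 6.76% ± 0.66 with vehicle (SD, n = 10 each, permutation p = 0.0159, adjusted p = 0.0768).

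With lithium in WT 325 genes rose and 231 fell. Banp rose by 0.53 (SE 0.0598, adjusted p = 1.03e-07), and Hif3a rose from 145 ± 39.6 (SD, n = 10) to 338 ± 46.4 (SD, n = 8), a log2 difference of 1.25 with adjusted p = 7.92e-07 by limma. Others that rose were Paqr8 (0.39), Zbtb16 (0.94), Map3k6 (2.28-fold), Gpt2 (0.38), an alanine aminotransferase, Fkbp5 (1.02), Sgsm1 (0.35), Prr5 (0.66), Adam8 (0.70), Pfkfb3 (0.41), a regulator of glycolysis, and Cables1 (0.35). Those that fell were Mlip (-0.37), Apbb1ip (-0.52), Prr16 (-0.63), the proneural factor Neurog2 (-1.02), Zc3h6 (-0.47), Nectin3 (-0.48), Depp1 (-1.43), Cdh10 (-0.32), Samd1 (-0.33), Pla2g4e (-0.50), Ctnnb1 (-0.22) and Nim1k (-0.21). The adjusted p of the named genes was at most 0.000437. The count of 556 was 229 when the compared groups were fitted alone, and 272, 347 and 357 without WT lithium female 4, WT lithium male 3 and WT lithium male 4.

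In WT with lithium, genes of the unfolded protein and integrated stress response rose in 15 of 33 and 18 did not pass (17 rose adjusted over the list alone), such as Hspa5 (0.50), Dnajc3 (0.29), Pdia4 (0.50) and Dnajb11 (0.20), with camera adjusted p = 9.97e-13 and adjusted p = 0.111 with an estimated correlation. Of 20 glucocorticoid-responsive genes 7 rose and 13 did not pass (8 rose and 1 fell adjusted over the list alone), such as Zbtb16, Fkbp5 and Pla2g3 (0.71), with camera adjusted p = 4.97e-08 and adjusted p = 0.2 with an estimated correlation. Cholesterol biosynthesis genes fell in 3 of 25 (6 adjusted over the list alone), namely Insig1 (-0.30), Hmgcs1 (-0.21) and Stard4 (-0.20), with camera adjusted p = 5.22e-05 and adjusted p = 0.67 with an estimated correlation. Astrocyte markers rose in 4 of 25 and fell in 1 (5 and 1 adjusted over the list alone), with Gjb6 (0.38), Htra1 (0.24) and Fgfr3 (0.22) higher and Sox9 (-0.32) lower (camera adjusted p = 0.00142, and adjusted p = 0.691 with an estimated correlation).

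The test of whether lithium acts differently in HT and WT passed 0 genes by limma, with 2320 at an unadjusted p under 0.05. On 54 libraries limma, edgeR and DESeq2 passed 0, 0 and 0, and without WT lithium female 2 or WT lithium female 1 the count was 37 or 31. The larger number of genes in HT than in WT with lithium is therefore not shown to be a difference between the genotypes.

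Genes in common between the drug comparisons were set against permuted data, in which the top genes of each comparison, taken to the real lengths, were compared in 100 draws with the real data counted as 1. This test was chosen after the lists were seen. In all 4 drug comparisons 44 genes rose, against a highest value of 16 in the other draws. These included Hif3a, Paqr8, Ccdc141, Dnajc3, Paqr5, Mertk, Sult1a1 and Plin4, which were chosen after their values were seen. Another 14 genes fell in all 4, against a highest value of 13, among them Insig1, Depp1, Ahcy and Stard4. Of the 44, 40 still rose in all 4 with the olfactory bulb level as a covariate and 19 with the exon length slope, and of the 14, 11 and 4 still fell.

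Fluoxetine in HT and in WT, which have no library in common, both raised 200 genes, as many as in 3 of 100 draws, and both lowered 243, as in 1 draw. Lithium in HT and WT both raised 176 and lowered 84, as in 1 draw each. Across genes r was 0.25 for fluoxetine (permutation p of the covariance = 0.0594) and 0.26 for lithium (permutation p of the covariance = 0.0198). The permutation p beside each r below is also that of the covariance. Fluoxetine in WT and lithium in HT, also without a common library, both raised 241 and lowered 186, as in 1 draw each (r = 0.25, permutation p = 0.139). Fluoxetine in HT and lithium in WT shared less, 68 raised and 23 lowered, as many as in 7 and 30 draws (r = 0.02, permutation p = 0.97). The pairs with the same vehicle libraries shared 433 and 368 in HT, as in 23 and 18 draws (r = 0.57, permutation p = 0.0594), and 126 and 56 in WT, as in 11 and 42 draws (r = 0.53, permutation p = 0.139).

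Whether a drug moves genes back against the genotype was asked by correlating the effect of genotype under vehicle with the drug effect in HT. Across genes r was -0.52 for fluoxetine and -0.51 for lithium. Both effects contain the HT vehicle libraries with opposite sign, so a negative value arises with no biological relation, and permuted data gave means of -0.49 and -0.49. The covariance was -0.0184 for fluoxetine against a mean of -0.0112 in permuted data (permutation p = 0.198), and -0.0184 for lithium against -0.00979 (p = 0.0396, kept under 0.05 only without HT lithium female 2, male 1 or male 2 or WT vehicle female 1). With the HT vehicle libraries divided between both effects, the mean r was -0.22 and -0.21. Single splits ran from -0.368 to -0.00256 for fluoxetine and from -0.331 to -0.0148 for lithium. Both parts come from the same group, and no permuted data were made for these splits, so they do not decide the question.

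Differences between the sexes were tested for 5 effects. The test for lithium in WT passed 486 genes, 172 with a higher and 314 with a lower effect in males. Tbck (0.39), Rpgrip1l (0.55) and Nalcn (0.46), a sodium leak channel, were higher, and the ribosomal protein genes Rpl35a (-0.71), Rps18 (-0.54) and Rpl26 (-0.56) lower, with adjusted p from 0.000745 to 0.00516. The count was 0 with the compared groups fitted alone, 0 with the exon length slope as a covariate, 59 without WT lithium female 3 and 1895 without WT lithium female 1. It was 1191 and 986 without WT vehicle female 1 and female 4, and 114 to 311 without any 1 of WT lithium female 4 and male 1, 2 and 3, and WT vehicle female 2, 3 and 5 and male 1, 2 and 5. The sex difference passed 0 genes by limma (1 without HT vehicle female 4, WT vehicle male 1 or WT vehicle male 2 for the genotype) for genotype under vehicle, fluoxetine in HT, fluoxetine in WT and lithium in HT, with 1012, 400, 745 and 669 genes at an unadjusted p under 0.05. On 54 libraries limma and edgeR passed 0 in each, and DESeq2 1, 0, 0 and 0. Within 1 sex, fluoxetine in HT passed 269 genes in females and 170 in males, fluoxetine in WT 139 and 258, lithium in HT 1235 and 197, and lithium in WT 302 and 523. Genotype under vehicle passed 2 genes in females and, by limma, 0 in males (996 at an unadjusted p under 0.05, and 0, 0 and 1 by limma, edgeR and DESeq2 on 54 libraries). These counts moved with the setting. With the compared groups fitted alone, fluoxetine in HT passed 0 in females by limma and 38 in males, fluoxetine in WT males 104, lithium in HT females 804 and lithium in WT females 12. With the exon length slope as a covariate, fluoxetine in HT females passed 674, fluoxetine in WT males 6, lithium in HT females 439 and lithium in WT males 23. On 54 libraries limma passed 7 and 65 in HT males with fluoxetine and lithium, and 621 in HT females with lithium.

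Single libraries moved the counts within 1 sex. Fluoxetine in HT females passed 0 without HT fluoxetine female 1 or HT vehicle female 3, 9 and 93 without HT fluoxetine female 2 and 3, 121 without HT vehicle female 5, 405 without HT fluoxetine female 5 and 447 without HT vehicle female 2. In HT males it passed 39 and 68 without HT fluoxetine male 1 and 5, and 69, 102, 43 and 64 without HT vehicle male 1, 3, 4 and 5. Fluoxetine in WT females passed 64 to 87 without any 1 of WT fluoxetine female 1, 3 and 4 and WT vehicle female 1, 4 and 5, and in WT males 93 to 167 without any 1 of WT fluoxetine male 3, 4 and 5 and WT vehicle male 4 and 5. Lithium in HT females passed 424 to 725 without any 1 of HT lithium female 3, 4 and 5 and HT vehicle female 1, 2 and 3, and in HT males 95 to 129 without any 1 of HT lithium male 2 and 5 and HT vehicle male 4 and 5. Lithium in WT females passed 1729, 507, 28 and 6 without WT lithium female 1, 2, 3 and 4, and 549, 164, 96 and 137 without WT vehicle female 1, 2, 3 and 5. In WT males it passed 332, 167 and 160 without WT lithium male 1, 2 and 3, and 323 and 153 without WT vehicle male 4 and 5. Genotype under vehicle in females passed 4 without WT vehicle female 4 and by limma 0 without any 1 of HT vehicle female 1, 2, 3 and 5 and WT vehicle female 1, 3 and 5, and in males 1 without WT vehicle male 1 or 2.

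Libraries differed in how much olfactory bulb RNA they held. Doc2g, a gene of olfactory bulb projection neurons, ranged from 37.1 to 3566 normalised counts, with 9 libraries under 100. HT vehicle ran from 458 to 1995 and WT lithium from 327 to 1998, without a library that low, while each of the other 4 groups of genotype and treatment had at least 1 under 100. The first component of what remained after group means held 18.6% of the variance and the second 5.99%. The olfactory bulb level differed by -1.56 with fluoxetine in HT (permutation p = 0.0718) and by 0.89 in WT (permutation p = 0.362), and by -1.28 with lithium in HT (permutation p = 0.137) and 1.13 in WT (permutation p = 0.217). The exon length slope was higher by 0.0317 with lithium in HT (permutation p = 0.0192, adjusted p = 0.0768), where ribosomal protein genes fell. With that slope as a covariate camera still passed 56 of the 76 list calls, and with the olfactory bulb level 53. None of the 76 list calls passed with an estimated correlation, and in each of the 7 comparisons at least 11 of 100 splits of the same libraries, the real one included, passed as many lists.

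**Figure D3:**
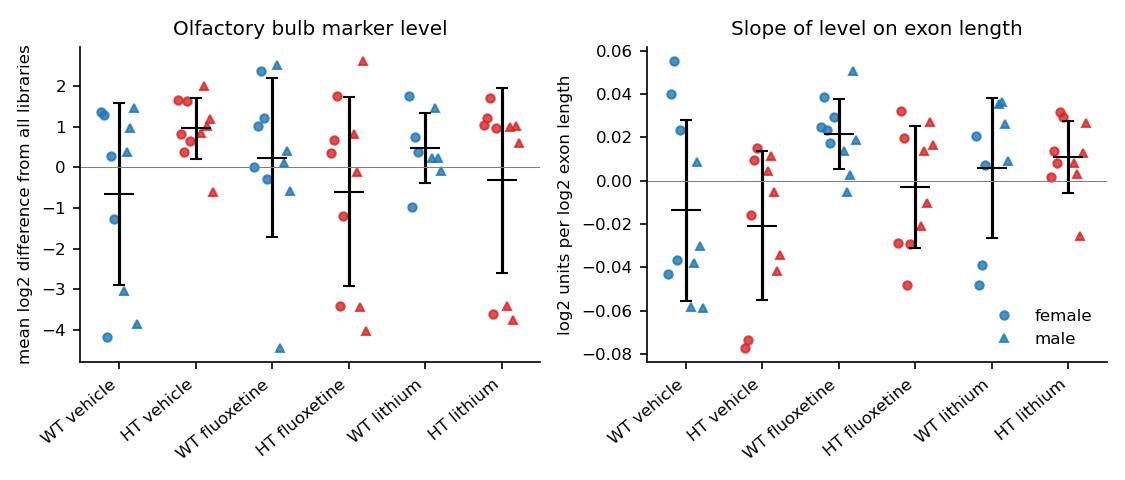
Olfactory bulb marker level (mean log2 difference from all libraries) and slope of log2 level on log2 exon length in each library by group, with circles for females, triangles for males and the mean ± SD in black. The HT vehicle libraries averaged 0.96 in olfactory bulb level and the WT vehicle libraries -0.66.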

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

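The length and olfactory bulb tests of the lithium sex difference, the permuted draws for genes common to both drugs, and the number of splits that match each single list were chosen after the result was seen. The genes common to both drugs and the Pisd copies were also picked after their values were seen, with the predictions of their other tests written before the tests were run. For the genes near centromeres and the overlap of 68 genes the reading was made more cautious afterwards, because the value met the written bound by less than its spread. For the stretch linked to Kmt5b it was made more cautious because the written bound, a Fisher p above the threshold and copies on other chromosomes, leaves open a linked variant that acts on those copies or a linked copy that the annotation lacks. For the exon length trend it was made more cautious because part of the differences remained with the covariate.

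Across 84 groups in 14 measures, 8 had a library further from its group than a 95% level allows, and such a level marks about 1 group in 20 by chance. WT fluoxetine male 5 had 30.09 M reads, the next having 26.49. HT lithium male 3 had a slope on exon length of -0.02548 against a next value of 0.001505. WT fluoxetine male 2 had an olfactory bulb level of -4.436 against -0.5865. Striatal marker levels of 1.161 in HT fluoxetine female 2 (next 0.391) and 0.6586 in WT vehicle female 5 (next -0.006397) stood apart. Fkbp5 was at 1114 in WT vehicle male 3 (next 713.1), Fos at 1326 in HT lithium female 2 (next 890.5) and Doc2g at 3505 in HT fluoxetine male 4 (next 1849).

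The test of the difference between HT and WT in the fluoxetine effect passed 7 genes, including Slco1a4 (0.467) and Mpeg1 (0.324). Camera passed 13 lists for that difference. Higher effects in HT had medians of 0.402 for mitochondrially encoded genes, 0.194 for microglia, 0.133 for astrocyte, 0.148 for endothelial and mural, 0.239 for oligodendrocyte and myelin and 0.175 for striatal markers, 0.0482 for cholesterol biosynthesis and 0.121 for immediate early genes. Lower effects had medians of -0.107 for lysine methyltransferases and demethylases, -0.0844 for autism risk genes, -0.065 for glutamate receptors, -0.301 for olfactory bulb and thalamus markers and -0.0702 for the unfolded protein response. For mitochondrially encoded genes 14 of 15 rose adjusted over the list alone and 0 over all genes, and for microglia markers 10 of 27 rose adjusted over the list alone and 2 over all genes. With an estimated correlation these 2 lists had adjusted p = 0.2, and the other 11 had adjusted p of 0.352 or more. The cholesterol, immediate early, olfactory bulb, striatal and unfolded protein calls, 5 of 13, ended with a mean of at least 100, the exon length slope or the olfactory bulb level.

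Camera passed 14 lists for the difference between HT and WT in the lithium effect. By limma 0 genes passed (2320 at an unadjusted p under 0.05, and 0 by edgeR and DESeq2 on 54 libraries). Higher effects in HT had medians of 0.393 for mitochondrially encoded genes, 0.108 for GABA receptors and 0.0798 for the circadian clock. Lower effects had medians of -0.129 for ribosomal proteins, -0.111 for the unfolded protein response, -0.0742 for nuclear oxidative phosphorylation, -0.243 for cell cycle genes, -0.217 for meningeal, -0.07 for endothelial, -0.0956 for oligodendrocyte precursor, -0.387 for olfactory bulb, -0.139 for oligodendrocyte, -0.314 for blood and -0.0658 for astrocyte markers. With an estimated correlation the adjusted p of these lists was 0.352 or more. With a mean of at least 100, the exon length slope, the olfactory bulb level or the replicate block 10 of the 14 calls ended. Those left were mitochondrially encoded, ribosomal protein, unfolded protein response and nuclear oxidative phosphorylation genes. As small a p for these lists came in 4, 11, 4 and 32 of 100 splits of the same libraries, the real one included.

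The sex difference of lithium in WT passed 486 genes, such as Tbck (0.388), Rpgrip1l (0.548), Nalcn (0.456), Rpl35a (-0.71), Rps18 (-0.543) and Rpl26 (-0.562). Higher calls had a median exon length of 10060 bases and lower calls 1838, against 4196 for all genes tested, and with the slope on exon length as a covariate 0 genes passed by limma while the median size of the 486 differences went from 0.44 (median SE 0.111) to 0.22 (median SE 0.0935), so the call ended because the differences shrank, with all 486 keeping their sign. With the olfactory bulb level as a covariate 868 genes passed. That counts all calls and not how many of the 486 remained, so tissue of the olfactory bulb was not excluded as a cause. The mean slope on exon length was 0.0079 in WT vehicle females and -0.0353 in males, and -0.0148 and 0.0268 with lithium (SD 0.0128 to 0.0449). In 40 libraries outside the comparison the called genes followed the slope (r = 0.88), as long genes set against short ones would in any case. A trend with gene length between libraries may account for part or all of this difference. It cannot be told apart from a difference between the sexes in the response to lithium. What remained with the covariate exceeded its SE, but only in genes picked for a large difference in these same libraries, so it does not decide.

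In all 4 drug comparisons 44 genes rose, among them Hif3a (1.07, 1.32, 1.49 and 1.25 for fluoxetine in HT and WT and lithium in HT and WT) and Plin4 (1.69, 1.64, 1.93 and 1.73). Olfactory bulb tissue as the whole cause was excluded, since 40 of the 44 still rose in all 4 with its level as a covariate. Vehicle libraries shared between comparisons, with the structure that libraries keep after group means are removed, were excluded as the whole cause: 1 of 100 draws of permuted residuals, the real data, had 44 genes in common, and the highest other had 16. The pair of fluoxetine in HT and lithium in WT, which share no library, by itself does not exclude it, with 68 genes raised by both (exact Poisson interval 52.8 to 86.2, which covers counting error only) and as many in 7 of 100 draws. The exon length trend cannot be told apart, with 19 of 44 still rising in all 4 under that covariate. A response common to both drugs, and shared litters or handling, which the labels do not give, stay open as causes and may each contribute.

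Pisd-ps1, Pisd-ps2 and Pisd were higher in libraries labelled HT. Reads moved among these 3 were excluded as the whole cause, since each was higher and their summed count therefore rose too, by 0.495 (SE 0.0388, n = 30 and n = 28, limma p = 1.6e-17). The sum does not cover reads exchanged with a further copy outside these 3. A variant linked to Kmt5b on chromosome 19 cannot be told apart: the annotated copies lie on chromosomes 5, 11 and 17, and 0 of 257 genes within 10 Mb of Kmt5b passed against 78 of 16411 elsewhere (Fisher's exact p = 0.636, two-sided), which leaves open a linked variant acting on the copies or a linked copy that the annotation lacks. The median of 300 other genes near centromeres was -0.0004 (SD of random medians 0.00301), with 1 of 300 passing, against 0.88 for Pisd-ps1 and 0.44 for Pisd-ps2. That argues against a rise of these genes as a class as the cause. Whether the class is higher in HT by a small amount cannot be told, its median lying at percentile 92.4 of 10000 random sets, within 1 SD of the bound. Another genomic difference between the HT and WT mice, or an effect of the genotype, may underlie it, and neither was tested.

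How often other splits of the same libraries passed as many genes was counted in 100 splits each, the real one included. As a division of single libraries, chance was excluded for genotype over all treatments (78 genes, highest other split 2). The same held for fluoxetine in HT (2134, 1296) and lithium in HT (2345, 290). Each was matched by 1 split, the real one. Fluoxetine in WT (1232, 732) and genotype under fluoxetine (102, 97) were also matched only by the real one. Chance was not clearly excluded for them. Without WT vehicle female 4 fluoxetine in WT passed 668, under the highest other split, and genotype under fluoxetine exceeded that split narrowly. No share was adjusted for the number of comparisons. For all of these 0 of 99 other splits had as many (exact 95% binomial interval 0 to 3.66%). The splits moved single libraries, so for drug effects they cannot speak to chance differences between litters, which the labels do not give. Nor was chance clearly excluded for genotype under vehicle (8, 890) and under lithium (10, 1351), each matched by 4 (interval over the other splits 0.629 to 8.6%), or for lithium in WT (556, 2023), fluoxetine by genotype (7, 164) and the sex difference of lithium in WT (486, 3797), each matched by 3 (0.246 to 7.11%). In these 5 at least 1 split passed over 3 times the real count, which points to a structure of the samples apart from their groups. The splits cannot speak to chance for lithium by genotype (0, 369) or the sex differences of genotype (0, 7), fluoxetine in HT (0, 30), fluoxetine in WT (0, 28) and lithium in HT (0, 8), because with a real count of 0 by limma all 100 splits must pass as many.

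Within 1 sex the splits again divided single libraries and not litters. In that sense chance was excluded for fluoxetine in WT females (139, highest other split 2). The same held for lithium in HT females (1235, 331) and males (197, 3). Each was matched by 1 split, the real one. Fluoxetine (258, 142) and lithium (523, 405) in WT males were also matched only by the real one. Without WT vehicle male 5 they passed 93 and 153, under the highest other split, so chance was not clearly excluded for them. Nor was chance clearly excluded for fluoxetine in HT females (269, 1874, matched by 4) or males (170, 280, matched by 3), with the same intervals as above. It was not excluded for lithium in WT females (302, 2685, matched by 8) or genotype under vehicle in females (2, 1714, matched by 6). For genotype in males (0, 1, matched by 100) the real count of 0 by limma leaves nothing to test. In fluoxetine in HT females, lithium in WT females and genotype in females, 1, 3 and 5 splits passed over 3 times the real count, which again points to sample structure.

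Gene lists passed as often in other splits. Adjusted within each comparison, the lists passed were 11 for genotype under vehicle (highest other split 17, matched by 59 of 100 splits), 8 for fluoxetine in HT (22, matched by 87), 12 for fluoxetine in WT (18, matched by 32), 12 for lithium in HT (17, matched by 31), 6 for lithium in WT (19, matched by 94), 13 for fluoxetine by genotype (20, matched by 39) and 15 for lithium by genotype (18, matched by 11). Chance was excluded for none of these counts. Single lists were then set against their own p in the same splits: of the 76 passed lists, 13 were matched in under 5 of 100 splits, 12 in 5 to 9 and 51 in 10 or more (up to 67). Those matched in 10 or more include oligodendrocyte (25), microglia (22) and ribosomal protein genes (15) with fluoxetine in HT, and ribosomal protein (19), endothelial (20) and autism risk genes (30) with fluoxetine in WT. Cholesterol biosynthesis and immediate early genes with fluoxetine in WT, glucocorticoid-responsive genes with lithium in WT and mitochondrially encoded genes under vehicle and in fluoxetine by genotype had as small a p in 1 of 100 splits, the real one. The unfolded protein response with lithium in WT was matched in 2, cell cycle and ribosomal protein genes with lithium in HT in 4 each, and immediate early genes with fluoxetine in HT in 9. These were picked out of 238 after they were seen, and among 238 some are small by chance. The 2 results of mitochondrially encoded genes contain the same vehicle libraries.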

How the results depend on the processing

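Counts of genes depended on the setting more than named genes did, which the choice of genes largely fixed. Apart from Kmt5b, named genes were picked for the smallest p in these same libraries. Their stability in refits of those libraries is therefore no separate support. Of 141 values of named genes, 0 changed direction in any setting (133 with a mean of at least 100), and those no longer past the threshold numbered 0 with other pseudocounts, without a filter, with a mean of at least 100 or with 2 surrogate variables, 11 with quantile normalisation, 15 with the compared groups alone and 16 with edgeR. The planned surrogate variables on counts, size factors of other kinds and the count filter applied to counts only and were not run as planned. Quantile normalisation moved the median of all genes by under 0.01. The causes of the values given next were not tested.

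Values are total genes passed. With quantile normalisation the genotype comparisons passed 4 (vehicle), 36 (fluoxetine), 2 (lithium) and 42 (all treatments). With the compared groups alone they passed 1, 7 and 4 under vehicle, fluoxetine and lithium, lithium in WT 229, fluoxetine by genotype 0, lithium by genotype 1, the sex difference of lithium 1 in HT and 0 in WT, and effects within each sex 1845 in place of 3095. With the replicate number as a block, genotype passed 2 under vehicle (1 in females) and 3 under lithium, and lithium in WT females 196. The other counts stayed within 1.5 times. The numbers did not pair samples: 9 of 48 same-numbered pairs had a correlation over 0.1 and 8 of 58 libraries matched best with their own number. With the block 81 lists passed, 74 of them among the 76. With the striatal covariate genotype passed 2, 27 and 23 under vehicle, fluoxetine and lithium. Genotype under lithium passed 3 without a filter, 2 with a mean of at least 100 and 4 with a pseudocount of 10. Without the trend fluoxetine by genotype passed 1. With an estimated correlation 0 of 238 list tests passed camera. The correlation of the genotype effect with the lithium effect was -0.558 (permutation p of the covariance = 0.0594) with a mean of at least 100, and -0.215 with the HT vehicle libraries split, where that with fluoxetine was -0.223.

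All other settings were chosen after seeing the data. With the olfactory bulb covariate genotype passed 4 (vehicle), 225 (fluoxetine, 105 higher and 120 lower), 32 (lithium) and 188 (all), fluoxetine in HT 4088, fluoxetine by genotype 1, the sex difference of lithium in WT 868 and effects within each sex 6129. With the exon length covariate genotype passed 29, 14, 18 and 225, fluoxetine in WT 273, fluoxetine by genotype 12 and the sex difference of lithium in WT 0. With both, genotype passed 5 (vehicle), 52 (lithium) and 357 (all), fluoxetine in HT 3809, fluoxetine in WT 362, lithium in WT 1105, fluoxetine by genotype 1 and the sex difference of lithium in WT 2. With 2 surrogate variables genotype passed 19, 445 (180 higher, 265 lower), 61 and 262, fluoxetine in HT 3924, lithium in HT 3555, lithium in WT 958, fluoxetine by genotype 17, the sex difference of lithium in WT 1256 and effects within each sex 7454. Kmt5b passed, still higher in HT, with each of these 4 (its unadjusted p over all settings ran from 1.74e-07 to 0.0272).

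Without the 2 libraries of highest olfactory bulb level and the 2 of lowest slope, genotype passed 235 under vehicle (67 higher, 168 lower) and 197 under fluoxetine (78 higher, 119 lower), fluoxetine by genotype 482 (177 higher, 305 lower), and the sex difference in WT 1 for fluoxetine and 932 for lithium. Without the first 2 and WT lithium female 3 and 4, genotype passed 93 (vehicle, 29 higher and 64 lower), 3 (lithium) and 129 (all), lithium in WT 242, fluoxetine by genotype 29, and the sex difference in WT 2 for fluoxetine and 26 for lithium. On 54 libraries limma passed 0 for genotype under vehicle, 2 under lithium, 789 for fluoxetine in HT, 1061 for lithium in HT and 0 for fluoxetine by genotype. There edgeR passed 1, 66, 2 and 48 for genotype under vehicle, fluoxetine, lithium and all, 783 for fluoxetine in HT, 995 for lithium in HT, 0 for fluoxetine by genotype and 2051 within each sex. There DESeq2 passed 165 and 22 for genotype under fluoxetine and lithium, 1002 for fluoxetine in HT, 1258 for lithium in HT, 24 for fluoxetine by genotype, and 1 and 990 for the sex difference of genotype and of lithium in WT.

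Leaving out each library in turn gave 2 to 25 genes for genotype under vehicle, 11 to 172 under fluoxetine, 2 to 211 under lithium and 65 to 122 over all treatments. It gave 1353 to 2276 for fluoxetine in HT, 668 to 1629 for fluoxetine in WT, 1644 to 2691 for lithium in HT and 272 to 771 for lithium in WT. It gave 1 to 46 for fluoxetine by genotype and 0 to 37 for lithium by genotype, 0 to 1 for the sex difference of genotype, 0 to 0 for those of fluoxetine in HT and WT and lithium in HT, and 59 to 1895 for that of lithium in WT. Effects within each sex ran from 2209 to 5120, 5120 without WT lithium female 1. Kmt5b ran from 0.0669 to 0.0866, and the correlations with the fluoxetine and lithium effects from -0.572 to -0.458 (permutation p of the covariance = 0.0396 without HT fluoxetine female 3) and from -0.556 to -0.453. Among named genes, those of genotype under vehicle except Slco1a4 lost their call in 12 to 15 of 20 such fits, Mpeg1 in 18 of 40, Trappc11 in 14 and Pik3cb in 3 of 58.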

Other observations

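Further lists passed camera without having been described. Of 29 genes of the interferon response and MHC class I, 4 fell with lithium in HT (6 adjusted over the list alone), such as Oas1a (-0.62), with camera adjusted p = 0.02 and adjusted p = 0.825 with an estimated correlation. Of 24 meningeal and fibroblast markers Igfbp2 fell there (-0.32, 1 adjusted over the list alone), with camera adjusted p = 0.0146 and adjusted p = 0.856 with an estimated correlation. Of 43 lysine methyltransferases and demethylases 2 rose with fluoxetine in WT (8 rose and 1 fell adjusted over the list alone), Nsd3 (0.15) and Dot1l (0.24), with camera adjusted p = 0.000604 and adjusted p = 0.823 with an estimated correlation. With lithium in WT the red cell anion exchanger gene Slc4a1 rose (adjusted p = 0.0149), 1 of 6 blood markers (1 adjusted over the list alone, camera adjusted p = 0.00161, and adjusted p = 0.67 with an estimated correlation). Choroid plexus markers with fluoxetine in WT had a median of 0.293, with 0 of 14 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.0384, and adjusted p = 0.691 with an estimated correlation). With the exon length slope as a covariate, chosen after seeing the data, the interferon (adjusted p = 0.1), meningeal (0.0655), methyltransferase (0.223) and choroid plexus (0.123) calls ended, and with the olfactory bulb level the interferon (0.0967), meningeal (0.138) and choroid plexus (0.0656) calls.

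Nuclear genes of oxidative phosphorylation fell in 5 of 77 with fluoxetine in WT (5 adjusted over the list alone), such as Atp5o (-0.14), and in 8 of 77 with lithium in HT, where 1 rose (6 fell adjusted over the list alone), such as Ndufv3 (-0.21). Camera gave adjusted p = 2.39e-11 and 0.000299, and with an estimated correlation adjusted p = 0.691 and 0.856. Both calls ended with the exon length slope as a covariate (adjusted p = 0.959 and 0.0516, the second in the opposite direction), as did those of mitochondrially encoded genes with fluoxetine in WT (0.1) and immediate early genes with lithium in WT (0.132), given next. Mitochondrially encoded genes were lower by camera with fluoxetine (adjusted p = 0.03) and lithium (adjusted p = 0.000604) in WT, with 0 of 15 past the threshold over all genes or adjusted over the list alone, and adjusted p = 0.853 and 0.714 with an estimated correlation. Immediate early genes with lithium in WT were lower by camera (median -0.153, adjusted p = 0.0438, and adjusted p = 0.856 with an estimated correlation), while the only member of 32 that passed, Maff (0.70), rose. Under vehicle, astrocyte and circadian clock genes were lower in HT by camera (adjusted p = 0.00776 and 0.0356), and ribosomal protein, lysine methyltransferase, perineuronal net and unfolded protein response genes higher (adjusted p = 0.00336, 0.0356, 0.0389 and 0.0335). In these 6 lists 0 members passed over all genes or adjusted over the list alone, and with an estimated correlation the adjusted p was 0.649 or more. With the olfactory bulb level as a covariate 5 of the 6 ended, with adjusted p = 0.245 (clock), 0.0967 (ribosomal protein), 0.761 (methyltransferase), 0.26 (perineuronal net) and 0.0519 (unfolded protein response). In 0 of the 7 planned comparisons did camera pass the KMT5 family (smallest adjusted p = 0.0519), excitatory neuron (0.0906), inhibitory neuron (0.05), heat shock (0.127), inositol (0.0804), presynaptic (0.06) or serotonin and monoamine (0.0826) lists, of which heat shock, presynaptic and serotonin and monoamine genes passed in the added comparison of genotype over all treatments.

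Fkbp5 stood at 641 ± 182 in WT vehicle and 810 ± 198 in HT vehicle (SD, n = 10 each), and rose with lithium in HT (0.71, SE 0.141, adjusted p = 0.000576) to 1302 ± 210 (SD, n = 10). With fluoxetine in HT it stood at 1047 ± 273 (SD, n = 10, a difference of 0.36 with adjusted p = 0.0846), and the difference between the genotypes in the fluoxetine effect was -0.51 (adjusted p = 0.344). These values were chosen after they were seen.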
